A study of Mus musculus with 11 samples.

How the data were processed

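CUT&RUN was profiled in 11 libraries from 2 mouse tumour cell lines, M00002 and M00001. In CUT&RUN an antibody brings a nuclease to its target in permeabilised cells, and the DNA released around the target is sequenced. Both lines carried an HA-tagged fusion, taken here as the ZFTA-RELA fusion named in the series title. HA and IgG control libraries came from both lines. H3K27ac with antibodies ac4729 and ac647, and p65, came from M00002. Cbp, p300 and Rpb1 with the antibodies written S2 and S5 came from M00001. The titles of the Cbp, p300, S2 and S5 libraries carry a code that those of HA and IgG of M00001 do not. Its meaning is not given in the sources used here, so a shared preparation of those 4 libraries cannot be excluded.

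Each library was deposited as 1 peak list, so peaks were called per sample and not on pooled samples. Trim Galore, FastQC, Bowtie2 2.3.5.1, MACS2, deepTools and the build mm10 are named, without settings, per the submitters' processing notes. The deposited lists hold for each peak a score, a fold enrichment at the summit (a ratio over the peak caller's background), a −log10 p-value, a −log10 q-value and the distance of the summit from the start, per the labels' tool list and the column order of MACS2. The smallest −log10 p in the deposited lists was 3, and no list was limited by q. The control used in calling is not given in the sources used here. The HA and p65 lists of M00002 carry a mark of 120 bp in their names and the other 9 lists do not. The meaning of the mark is not given in the sources used here, and it coincides with line for HA. Fold enrichment is the authors' value and was used here only to describe, rank or filter peaks within a list. The lists hold no read counts, so read depth is unknown and the number of peaks in a list is no measure of occupancy.

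Comparisons used chromosomes 1 to 19 and X, and other sequences were counted separately. Peaks within a list did not overlap each other. Peak sets were compared by overlap of at least 1 bp against 1000 random relocations of the query peaks within their chromosomes, one-sided, with the smallest possible p near 0.001. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. HA and IgG peaks of a line, without those that overlap each other, were compared in their overlap with each mark by Fisher's exact test, two-sided. HA peaks were ranked within a list into 5 equal classes of fold enrichment and the trend was tested with 10000 permutations, two-sided. Benjamini-Hochberg adjustment was applied within each family of tests and the threshold was 0.05. Peaks are not replicates, so every p-value compares these libraries, not conditions. HA and IgG had 2 libraries each, 1 per line, and every other target had 1.

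Genes were the 21631 protein-coding genes of GRCm38.p6, the assembly behind mm10, in a table of gene starts and ends. That table holds no strand, exons or sequence. The design fixed before the data were examined named the transcription start site; in its place a peak within 5 kb of either end of the gene was counted, and within 1 kb of either end for position. Motifs, exons and introns were not analysed here. A gene had HA when an HA peak without overlap with IgG of the same line lay within 5 kb of an end. Peaks at neighbouring genes can be counted for each of them. Polymerase at genes with and without HA was compared with a Cochran-Mantel-Haenszel odds ratio over 5 classes of gene length.

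The 16 gene lists, fixed before the data were examined, were ependymoma, NF-kappaB targets, radial glia, ependymal, neuron, oligodendrocyte lineage, astrocyte, microglia and leukocyte, endothelium, other tissues, Notch, Hedgehog, receptor tyrosine kinases, G1 cell cycle, imprinted and housekeeping. Of their 218 distinct genes, 216 were among the protein-coding genes; H19 and Meg3 were not. Lists were tested by Fisher's exact test against all other protein-coding genes. Where an empty cell made an odds ratio infinite, 0.5 was added to each cell. No gene was tested by itself, so no count adjusted over the list alone exists. The ependymoma list comes from what is known of this tumour type and is not independent of it.

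The rule for named genes was fixed before the data were examined. It took the 20 genes with the highest mean within-list rank of HA fold in both lines, up to 4 members of each list in that ranking, and the 10 genes with the highest ranks of HA, Cbp and p300 in M00001. It also took the 10 with the widest H3K27ac over an end, the 10 with the strongest p65 and neither HA nor IgG in M00002, and the 10 with the most gene body covered by S2 peaks. Genes that share a peak are named together.

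Alternatives were a 50% minimum overlap, −log10 q of at least 5, the 2000 strongest peaks (500 for HA against IgG), windows of 250 bp each side of the summit, relocation by 10 to 100 kb, removal of peaks that overlap IgG, gene windows of 1 kb and 25 kb, each HA library alone, marks of the other line, and the line as a stratum. Further alternatives were added after the data were seen: chromosome Y included, a peak within 500 bp counted, a peak anywhere in the gene, IgG of either line removed, and peaks near or far from gene ends only. The contrasts of HA peaks with and without p300, Cbp or p65, the widths of H3K27ac regions and the tests of gene families were also chosen after the data were seen.

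The code was tested on simulated data. For HA against p65 in M00002, with overlaps planted in 0%, 2% and 20% of 29937 peaks, the excess over relocation came out at -0.0626%, 1.99% and 20.0%. Of simulated lists of 15 genes among 21631, 2.3% of unchanged lists were called at an unadjusted 0.05, and 88.5% of lists with 60% bound against 20%. A direct search gave the same overlap call for all 300 peaks tried. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.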

Results

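The deposited lists describe where an HA-tagged fusion of ZFTA and RELA, the main oncogenic fusion of supratentorial ependymoma, was found in the genome of 2 mouse tumour lines, and which chromatin marks and proteins lay at the same sites. HA gave 30680 peaks in M00002 and 9365 in M00001, and IgG gave 7045 and 1806. In M00002, H3K27ac, a mark of active promoters and enhancers, gave 29626 peaks with antibody ac4729 and 16754 with ac647, and p65, the product of Rela, gave 16253. In M00001 the related coactivators Cbp and p300 gave 6608 and 6655 peaks. Rpb1, the largest subunit of RNA polymerase II, gave 22984 peaks with S2 and 11032 with S5. Phosphorylation at serine 2 and serine 5 of its tail is known from elongating and initiating polymerase. Median widths ran from 115 bp for HA in M00002 to 451 bp for H3K27ac with ac4729. Between 22.8% (IgG, M00001) and 86.5% (ac4729) of the peaks in a list had q below 0.01. Read depth is unknown.

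The first comparison asked whether HA sites were shared by the lines and differed from IgG. Among HA peaks free of IgG of the same line and within 5 kb of a gene end, the sites with the highest rank in both lines lay at Pcbp3, Mxra7, between Haus5 and Rbm42, and between Mad2l1bp and Rsph9. At one end of Pcbp3 (chromosome 10, 76761854 to 76962117), which encodes an RNA-binding protein, HA fold enrichment was 29.2 in M00002 (76961902 to 76962252) and 18.2 in M00001 (76961965 to 76962322). Beside Rbm42 on chromosome 7, the values were 32.0 (30650202 to 30650366) and 15.7 (30650162 to 30650370). At Zfp687, which encodes a zinc finger protein, they were 23.0 and 18.9, and at Sec61a1, which encodes the channel subunit of the endoplasmic reticulum translocon, 25.8 and 14.1. None of these genes had an IgG peak within 5 kb of an end in either line. Higher folds lay outside this ranking, up to 111 in M00002 and 65.8 in M00001, and of the 100 HA peaks with the highest fold 53 and 89 overlapped IgG of either line. The other genes of the ranking were Ddi2 with Rsc1a1, Ddost with Kif17, Ccdc159 with Plppr2, Zbtb18, Brpf1 with Cpne9, and Klhdc3 with Mea1 and Rrp36.

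Of the HA peaks of M00001, 55.4% (95% interval 54.4 to 56.5) overlapped an HA peak of M00002, against 0.497% after relocation. In the other direction the share was 16.9% (16.5 to 17.4), against 0.142%. IgG peaks were shared too: 25.3% (23.1 to 27.5) of those of M00001 overlapped IgG of M00002, against 0.0991%. With −log10 q of at least 5 in both lists the order turned: 84.3% of 2803 HA peaks of M00001 were shared and 95.5% of 198 IgG peaks. HA overlapped IgG of its own line in 2.54% (2.37 to 2.73) of peaks in M00002 and 4.50% (4.07 to 4.97) in M00001. All 17 overlaps tested by relocation, in this and the next comparisons, reached the smallest permutation p of 0.001, also after adjustment. Relocation by 10 to 100 kb gave higher shares, 1.29% for HA of M00001 in M00002, 0.388% in the other direction and 1.01% for IgG. The 17 overlaps were then 13.4 to 64.5 times the relocated ones. HA peaks lay within 1 kb of a gene end in 18.3% of cases in M00002 and 22.8% in M00001, 5.81 and 7.18 times the relocated shares. For IgG the shares were 4.64% and 4.71%, 1.54 and 1.53 times the relocated ones. With −log10 q of at least 5, IgG fell to 0.986 and 1.01 times.

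An HA peak free of IgG lay within 5 kb of an end of 8581 genes in M00002 and 3528 in M00001. In both lines together there were 3069 such genes, against 1400 for independent sets (odds ratio 15.3), and 87.0% of the M00001 genes were among those of M00002. IgG of M00002 also lay more often at the 3069 genes, at 7.46% against 4.38% of other genes (odds ratio 1.76, exact p = 3.35e-12). For IgG of M00001 the shares were 1.73% and 1.38% (exact p = 0.140). The count of 3069 was 1925 with a 1 kb window, 6533 with 25 kb, 1398 with −log10 q of at least 5 and 719 with the 2000 strongest peaks of each list.

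NF-kappaB targets carried HA most often among the fixed lists with the 5 kb window. HA in both lines was found at 17 of 25 targets, 68.0% against 14.1% of other genes (odds ratio 12.9, Fisher's exact test, adjusted p = 2.03e-08). Ccl5 and Ccl2, which encode chemokines, had HA folds of 23.8 and 21.3 in M00002 and 10.8 and 10.4 in M00001. At Nfkbie, an inhibitor of NF-kappaB, they were 19.3 and 9.45, and at Nfkb2, a subunit of NF-kappaB, 13.0 and 9.84. The map of the Nfkb2 region (chromosome 19, 46300994 to 46312400) shows 2 HA peaks per line inside the gene. The folds given are from different sites, 46304541 to 46304757 in M00002 and 46305426 to 46305927 in M00001. The 8 targets outside the call were Ptgs2, Tnfaip3, Rel, Traf1, Vcam1, Nfkb1, Il6 and Cxcl10. HA was also found at 9 of 15 housekeeping genes (odds ratio 9.10, exact adjusted p = 0.000409), with Actb at folds of 18.9 and 12.8 and Gapdh, Eef1a1 and Pgk1 among them. It lay at 7 of 15 G1 cell cycle genes (odds ratio 5.30, exact adjusted p = 0.0138), led by Ccnd3, Cdkn1a, Ccne1 and Cdk6.

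The other lists did not pass. Among ependymoma genes 6 of 18 had HA in both lines, Hes1, Nfkb2, Notch1, Lhx2, Ephb2 and Relb, and among radial glia genes 6 of 18, with Sox9 (folds 16.3 and 7.28), Hes1 (11.3 and 8.07), Id3 and Notch1 in front (both exact adjusted p = 0.0875). Imprinted genes reached 5 of 13, with Peg10, Peg3, Gnas and Grb10 (exact adjusted p = 0.0875). The counts were 3 of 15 ependymal genes (Foxj1, Ccno and Gmnc), 1 of 15 neuron genes (Tubb3), 3 of 12 oligodendrocyte lineage genes (Myrf, Sox10 and Cnp) and 0 of 10 astrocyte genes. They were 3 of 12 microglia and leukocyte genes (Tmem119, Csf1r and Cd68), 2 of 10 endothelium genes (Egfl7 and Cldn5) and 1 of 15 genes of other tissues (Apoa2). Notch had 3 of 16 (Hes1, Dll3 and Notch1), Hedgehog 2 of 12 (Sufu and Smo) and receptor tyrosine kinases 3 of 16 (Ephb2, Erbb3 and Igf1r). Around L1cam, which encodes a cell adhesion protein known from this tumour, 0 peaks lay within 5 kb of either end in any of the 11 lists. Ccnd1 and Rela had HA peaks in M00002 and 0 in M00001. Near Gmnc, Csf1r, Cdk6 and Peg10 lay 1 IgG peak of M00002 each. At Sox10, Cnp and Gmnc the HA peak of M00001 had a −log10 q of only 0.110, 0.750 and 0.750. A call in both lines needed no shared site. At Cnp the HA peaks of the lines did not overlap each other. The strongest HA peaks of the lines also lay apart at Nfkb2, Sox10, Tubb3, Ephb2, Gmnc, Cdk6 and Cd68.

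When the background held only genes with H3K27ac of both antibodies within 1 kb of an end, 0 lists passed, and NF-kappaB targets had an odds ratio of 5.39 (exact adjusted p = 0.357). The G1 call was lost under 7 alternatives, and the housekeeping call also with the 2000 strongest peaks (odds ratio 4.48, exact adjusted p = 0.697). With the 25 kb window housekeeping genes led, at 12 of 15 (odds ratio 9.26), ahead of 17 of 25 NF-kappaB targets (4.92).

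**Figure D1:**
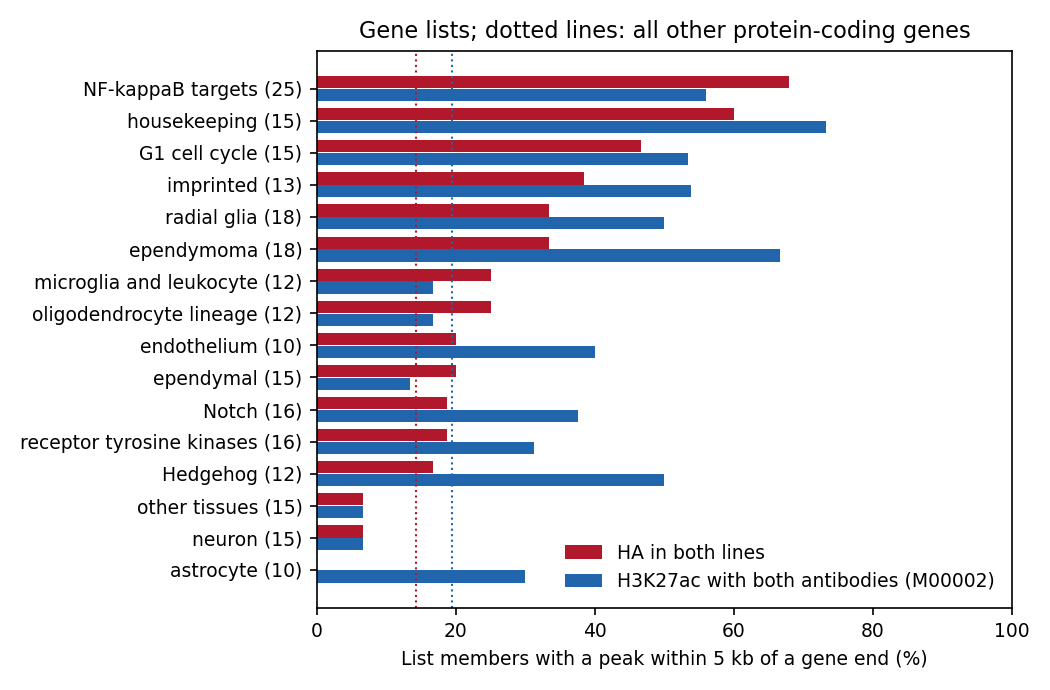
Percent of the members of each gene list (number of members in brackets) with HA in both lines (red) or H3K27ac with both antibodies in M00002 (blue) within 5 kb of a gene end; dotted lines give all other protein-coding genes. NF-kappaB targets reach 68.0% for HA and 56.0% for H3K27ac.

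**Figure D2:**
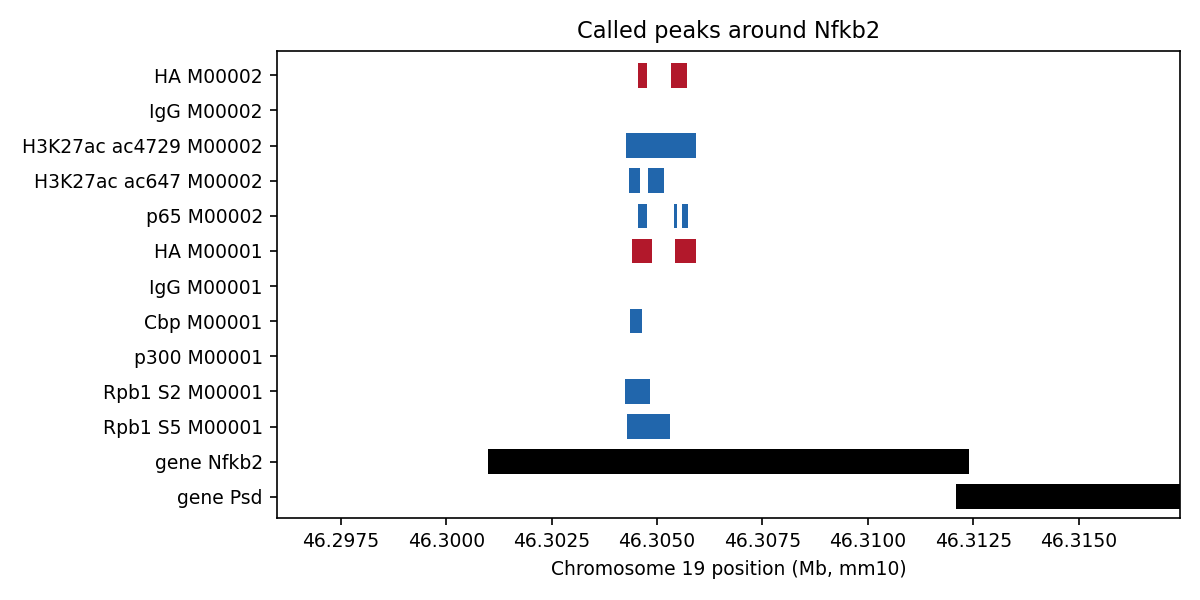
Called peaks (bars) of the 11 libraries against position on chromosome 19 in Mb, 5 kb beyond each end of Nfkb2, with genes in black, HA in red, IgG in grey and other targets in blue. HA, p65 and H3K27ac peaks lie together, with 0 IgG peaks.

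The second comparison asked what lay at HA sites in M00002. The 20 genes ranked highest for HA free of IgG in both lines all had p65: at Pcbp3 the p65 fold was 24.6, at Sec61a1 25.6, and at Zfp687 21.4. Of the HA peaks 33.7% (33.2 to 34.2) overlapped p65, against 0.192% after relocation (0.533% by 10 to 100 kb), and of the p65 peaks 64.7% (63.9 to 65.4) overlapped HA. The share with p65 rose from 2.19% in the lowest class of HA fold by 87.8 percentage points in the highest. Among the 3069 genes with HA in both lines 83.5% had p65, against 15.1% of other genes. p65 is both a protein of its own and the RELA part of the fusion.

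Of the 5366 genes with p65, 4704 also had HA and 623 had neither HA nor IgG in M00002. The strongest of these 623 was Ubqln1, with a p65 fold of 10.4, then Cdc42ep5 with Leng9 at 8.25, Zfp335 at 7.76 and Agpat3 at 7.71. Cfap70 with Mrps16, Trim67, Mettl26 and Stmn3 followed, between 7.19 and 6.39. HA of M00001 was present at Cdc42ep5 and Leng9, with a fold of 3.90.

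H3K27ac covered 24.2% (23.7 to 24.7) of HA peaks when both antibodies were required, against 0.467% after relocation (1.15% by 10 to 100 kb). The antibodies shared 72.9% (72.2 to 73.6) of the ac647 peaks and 37.6% (37.1 to 38.2) of the ac4729 peaks. From the lowest to the highest class of HA fold the share with ac4729 rose from 7.47% to 74.7% and that with ac647 from 4.06% to 52.8%. The widest H3K27ac over a gene end, averaged over the antibodies, was 2206 bp at Btbd19, 2026 bp at Sh2d3c, 1949 bp at Lmtk3 and 1878 bp at Ccm2. Eif4g2, BC029722 with Mmp24, Wfdc1 and C8g followed, all with HA in M00002, and Irgm1, an interferon-induced GTPase at 1740 bp, had 0 HA and 0 p65 peaks. Beside Eif4g2 and Wfdc1 lay 1 IgG peak each of M00002.

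H3K27ac of both antibodies lay at 12 of 18 ependymoma genes (exact adjusted p = 0.000133), 14 of 25 NF-kappaB targets (0.000295) and 11 of 15 housekeeping genes (0.000133). It passed also for 9 of 18 radial glia, 8 of 15 G1 cell cycle, 7 of 13 imprinted and 6 of 12 Hedgehog genes, with exact adjusted p of 0.0113, 0.0113, 0.0159 and 0.0389.

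HA peaks of M00002 without IgG overlap held ac4729 in 36.7% of cases against 5.50% of IgG peaks without HA (odds ratio 9.96, 8.83 to 11.2). For ac647 the shares were 21.1% and 10.2% (2.36, 2.15 to 2.59) and for p65 32.9% and 2.24% (21.4, 17.8 to 25.7). The odds ratio for ac4729 was 5.31 within 1 kb of gene ends and 41.2 with the 500 strongest peaks of each list, where all 404 HA peaks held p65. For ac647 it was between 2.08 and 2.84 under the alternatives within M00002. The HA and IgG libraries of M00001 gave higher odds ratios with these marks of M00002, 33.0 for ac4729, 15.6 for ac647 and 60.4 for p65, and the line as a stratum gave 11.9, 3.17 and 25.5.

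Contrasts chosen after the data were seen divided the HA peaks of M00002 by p65, leaving out those that overlap IgG of either line. An H3K27ac region with both antibodies was overlapped by 47.5% of 9577 HA peaks with p65 and 11.9% of 19570 without (odds ratio 6.69, 6.31 to 7.10). The odds ratio was 3.00 among HA peaks with −log10 q of at least 5, 2.71 within 1 kb of gene ends and 8.63 farther away. HA fold was not held equal, and the shares with p65 and with H3K27ac both rose with it. Of 10274 H3K27ac regions, 56.8% held HA in M00002. Those regions had a median width of 986 bp against 715 bp without HA, a difference of 271 bp, and with HA of M00001 the medians were 1090 and 804 bp. The permutation p was 0.0001, the smallest 10000 permutations can give. A wider region has more room for an overlap.

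**Figure D3:**
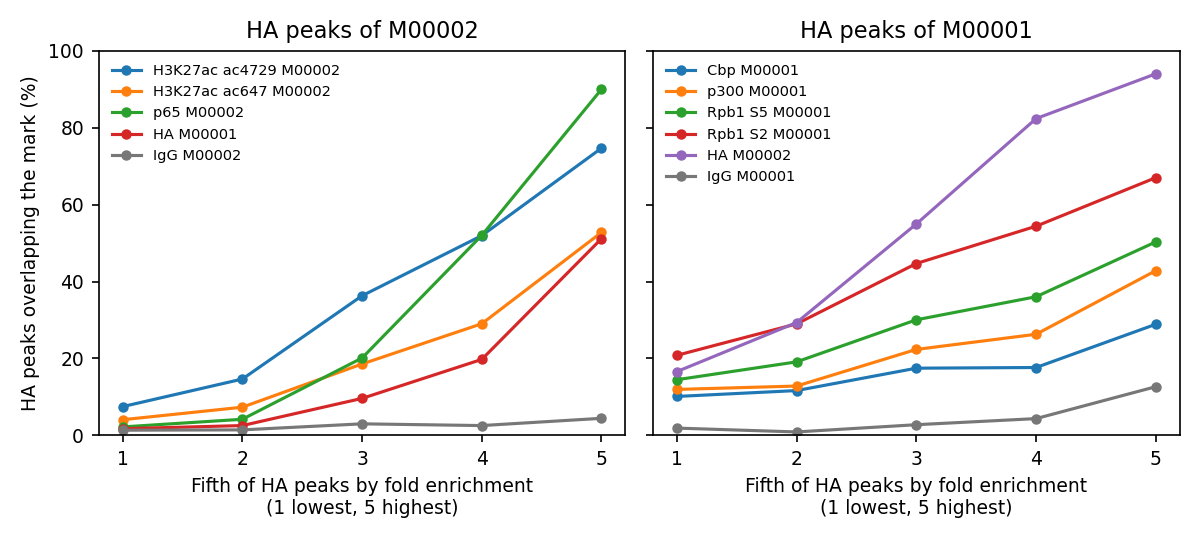
Percent of HA peaks that overlap each other list (y axis) in 5 equal classes of the authors' HA fold enrichment (x axis), for M00002 (left) and M00001 (right). In M00002 the share with ac4729 climbs from 7.47% to 74.7%, and IgG from 1.34% to 4.43%.

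The third comparison asked whether coactivators and polymerase lay at HA sites in M00001. The highest joint ranks of HA, Cbp and p300 were at Rps29, at Parp3 with Rrp9, and at Brpf1 with Cpne9, among 381 genes with all 3, free of IgG of the same line, within 5 kb of an end. Between Cpne9 and Brpf1, which encodes a chromatin reader protein, the folds were 17.6 for HA (chromosome 6, 113306351 to 113306841), 5.77 for Cbp and 7.88 for p300. At Parp3 they were 13.4, 7.70 and 6.98. Gtf2a1l, Inpp5a, Gstp2, and Rras with Scaf1 made up the rest. At Rps29, a ribosomal protein gene, HA of M00001 had a fold of 20.2 while HA of M00002 had 0 peaks, and the ac647 library of M00002 had a fold of 29.2. Near Gtf2a1l lay 2 IgG peaks of M00002 and 0 HA peaks of that line.

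Of the HA peaks of M00001, 17.1% overlapped Cbp, 23.2% (22.3 to 24.1) p300, 30.0% (29.0 to 31.0) S5 and 43.2% (42.1 to 44.2) S2, against at most 0.623% after relocation (1.80% by 10 to 100 kb). Of the Cbp peaks 29.2% overlapped p300 and 24.2% HA, and of the p300 peaks 31.9% overlapped HA. With −log10 q of at least 5 in both lists the HA shares were 53.1% for Cbp and 45.1% for p300, and 66.9% of Cbp peaks overlapped p300. Peaks that overlap IgG were kept there. Without the q limit, the 29.2% of Cbp peaks that overlapped p300 fell to 18.4% with peaks that overlap IgG of either line removed. Cbp and p300 lists held IgG peaks of either line in 19.7% and 17.1% of cases; with such peaks removed from all lists, 9.09% of HA peaks overlapped Cbp and 16.5% p300. From the lowest to the highest class of HA fold, Cbp rose from 10.1% to 28.9%, p300 from 11.9% to 42.8%, S5 from 14.5% to 50.3% and S2 from 20.8% to 67.0%. IgG of the same line rose from 1.88% to 12.6%. Without the HA peaks that overlap it, the rise was smaller, from 8.80% to 19.3% for Cbp and from 10.8% to 34.9% for p300.

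HA peaks without overlap with IgG of M00001 held Cbp in 13.8% of cases against 4.11% of IgG peaks without HA (odds ratio 3.75, 2.80 to 5.02). For p300 the shares were 20.2% and 3.27% (7.50, 5.44 to 10.4) and for S5 27.3% and 4.19% (8.57, 6.44 to 11.4). For S2 they were 41.1% and 6.20% (10.6, 8.31 to 13.4). HA peaks at IgG of M00002 were kept here. With IgG of either line removed from all lists, the HA shares were 9.09% for Cbp, 16.5% for p300, 24.3% for S5 and 38.6% for S2. No odds ratio against IgG was computed for that setting. Over the 500 strongest peaks, windows around summits, and peaks near or far from gene ends, the odds ratio ran from 3.72 to 4.79 for Cbp, 6.55 to 14.4 for p300, 5.58 to 17.5 for S5 and 6.92 to 20.8 for S2, the last 2 lowest far from ends and highest near them. With the line as a stratum, so that HA and IgG of M00002 enter as well, the odds ratios turned to 0.371 for Cbp and 0.822 for p300 and fell to 1.30 for S5 and 2.18 for S2. The HA and IgG libraries of M00002 alone gave 0.173 for Cbp, 0.481 for p300, 0.873 for S5 and 1.58 for S2. Without the peaks shared by HA and IgG, higher overlap of HA with Cbp and p300 thus held in M00001 and not across lines. In the whole lists of M00001 HA was not higher: 25.2% of IgG peaks overlapped Cbp and 24.4% p300, against 17.1% and 23.2% of HA peaks. For S5 and S2 the whole lists gave 25.1% and 26.6% of IgG peaks, against 30.0% and 43.2% of HA peaks. For Cbp, p300 and S5 the lines went in opposite directions. The odds ratio with the line as a stratum describes neither line there.

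In a division chosen after the data were seen, 412 HA peaks held both coactivators, 838 p300 only, 296 Cbp only and 5916 neither, with peaks that overlap IgG of either line left out. S5 was present at 75.7%, 59.5% and 42.9% of the first 3 classes. With p300 the share was 64.9% against 16.4% without (odds ratio 9.44, 8.25 to 10.8), and among peaks more than 1 kb from gene ends 52.6% against 8.65% (11.7). The odds ratio was 6.03 among HA peaks with −log10 q of at least 5. HA fold was not held equal: its median was 5.81 with both coactivators, 5.82 with p300 only, 4.72 with Cbp only and 3.98 with neither.

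**Figure D4:**
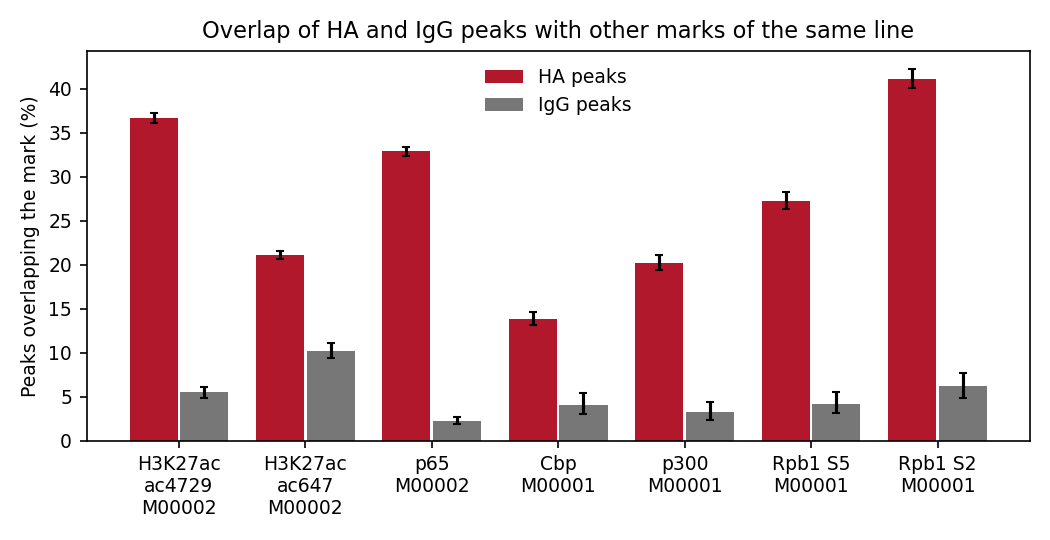
Percent of HA peaks (red) and IgG peaks (grey) of a line that overlap each other mark of the same line, without peaks that overlap between HA and IgG; error bars are exact 95% binomial intervals over peaks. S2 is highest for HA at 41.1%, against 6.20% for IgG.

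Polymerase lay more often at genes with HA in M00001. Of the 3069 genes with HA in both lines 90.7% had S2 and 33.1% p300 within 5 kb of an end, against 44.3% and 6.46% of other genes. S5 was within 1 kb of an end of 45.4% of 3566 genes with HA, IgG-overlapping peaks included, and of 16.1% of 18065 genes without (odds ratio over length classes 4.08, 3.78 to 4.41). For S2 near an end the shares were 70.5% and 34.9% (4.14, 3.82 to 4.48), and for S2 in the gene body 31.3% and 19.6% (2.18, 1.99 to 2.39). Near an end the odds ratios depended on the window that assigns HA to a gene: with 1 kb they were 7.97 for S5 and 11.3 for S2, and with 25 kb 2.68 and 2.76. For S2 in the gene body they were 1.59 and 2.53. The longest S2 cover of a gene body was 8295 bp at Aopep, then 8272 bp at Sfi1, 7578 bp at Tns3 and 7528 bp at Prdm16. Msi2, Tcf4, Zfhx3, Zmiz1, Col23a1 and Tead1 followed. Near Sfi1 lay 4 IgG peaks of M00002 and 2 of M00001. S2 was found at 0 of 10 endothelium genes (exact adjusted p = 0.0130), and at 13 of 15 genes each of the G1 cell cycle and housekeeping lists (both exact adjusted p = 0.0400). S5 passed for 10 of 13 imprinted, 10 of 15 G1 cell cycle and 11 of 15 housekeeping genes (exact adjusted p of 0.00242, 0.00960 and 0.00242). For Cbp and p300 no list passed, with the smallest exact adjusted p at 0.221 and 0.0746.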

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

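The tests that weigh explanations here were chosen after the results they concern were seen, except that of gene ends at HA peaks that overlap IgG.

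The HA against IgG contrast differed between the lines for all 7 marks (chi-square test of the ratio of odds ratios, largest adjusted p = 6.25e-05). The odds ratio of M00002 divided by that of M00001 was 0.302 for H3K27ac with ac4729, 0.151 for ac647, 0.354 for p65, 0.0460 for Cbp, 0.0641 for p300, 0.102 for S5 and 0.149 for S2. All lie below 1. They are lowest for Cbp, p300 and S5, measured in M00001, while S2 of that line and ac647 of M00002 are nearly equal. The contrast leaves out IgG peaks that overlap HA, 25.1% of those of M00001 and 11.1% of those of M00002. This step took the Cbp share of IgG peaks from 25.2% to 4.11% in M00001 and from 19.3% to 14.5% in M00002. For p65 it took the share from 16.5% to 1.42% and from 9.07% to 2.24%. How much of the difference between the lines follows from it was not tested. Cbp peaks lay on chromosome Y in 9.34% of cases, against 7.20% of IgG peaks of M00001 (exact adjusted p = 0.00622).

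Regions called in IgG run through these lists: of the 100 HA peaks of M00002 with the highest fold, 53 overlapped IgG of either line, and in the other non-IgG lists 55 to 98 of 100 did. The count of 53 restates the pattern. Regions called whatever the antibody do exist, as 225 HA peaks of M00002 were called in all 11 libraries. How many of the 53 are among them was not counted, so whether these are such regions stays open. HA peaks of M00002 that overlap IgG lay near a gene end less often than others, 4.20% against 18.6% (odds ratio 0.192, 0.134 to 0.274). IgG peaks lay there in only 4.64% of cases in M00002 and 4.71% in M00001, so peaks picked by IgG overlap would differ anyway. The values show only that few of these peaks lie near gene ends. Whether fusion binding at promoters is their origin is not decided by this ratio. IgG peaks of M00002 at Cbp peaks of M00001 without HA lay near a gene end in 2.65% of cases against 12.6% of other Cbp peaks (odds ratio 0.189, 0.102 to 0.351). All IgG peaks of M00002 together lay there in only 4.64% of cases, so this ratio leaves open whether background shared by the IgG list of M00002 and the M00001 lists lowers the contrast across lines. Differences between the lines themselves stay open and were not tested.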

How the results depend on the processing

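Of the recomputed values, 424 kept their direction and their side of the threshold or stayed within their spread, 32 reversed, 11 fell below the threshold, 2 rose past it and 7 moved. All overlaps with relocation, all trends over HA fold and all polymerase odds ratios (from 1.24 to 11.3) kept their direction under every alternative run. Motif alternatives were not run for lack of sequence. Contrasts added after the data were seen kept their direction under all alternatives run, with the odds ratio of H3K27ac at HA peaks with p65 from 2.71 to 8.63 and that of S5 with p300 from 6.03 to 12.8. With marks of the same line HA against IgG kept its direction too, with ac4729 from 5.31 to 41.2. Each of these alternatives left out the peaks that overlap between HA and IgG. In the whole lists of M00001 HA was not higher than IgG for Cbp or p300. The marks of the other line turned the HA against IgG odds ratio to 0.173 for Cbp, 0.481 for p300 and 0.873 for S5. With the replicate block, the line as a stratum, it was 0.371 for Cbp and 0.822 for p300. The block ended no other call, with 1.30 for S5 and 2.18 for S2. For Cbp, p300 and S5 the block joins lines of opposite direction, so its odds ratio describes neither. With −log10 q of at least 5, IgG near gene ends turned to 0.986 in M00002 and lost its call at 1.01 in M00001. Genes with HA in both lines numbered 1925 with 1 kb, 6533 with 25 kb, 1398 with −log10 q of at least 5, 719 with the 2000 strongest peaks, and 3528 to 8581 with either HA library alone. Of 3 lists, 1 passed with the 2000 strongest peaks and 0 with the H3K27ac background, which holds fewer genes. G1 lost its call with 1 kb (odds ratio 3.73), 25 kb (3.47), −log10 q of at least 5 (3.62), the 2000 strongest peaks (2.08), the H3K27ac background (1.19) and, added later, a peak anywhere in the gene (3.53) or IgG of either line removed (4.09).

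Lists that did not pass crossed an odds ratio of 1 at small counts. With 1 kb it was 0.931 for microglia and for Hedgehog, 0 for endothelium and receptor tyrosine kinases, 0.682 for Notch and 0.853 for imprinted. With 25 kb it was 1.54 for other tissues. With −log10 q of at least 5 it was 0 for ependymal, 1.03 for neuron and other tissues and 0.965 for receptor tyrosine kinases. With the 2000 strongest peaks it was 2.08 for other tissues and 0 for ependymoma, ependymal, endothelium, Notch, Hedgehog, receptor tyrosine kinases and imprinted. With HA of M00002 alone it was 1.01 for astrocyte. With the H3K27ac background it was 0.714 for ependymoma, 0.595 for receptor tyrosine kinases and imprinted, and 0 for Hedgehog, while ependymal and other tissues had no member left. Among alternatives added later it was 1.01 for neuron with a peak anywhere in the gene and 0.942 for ependymal with IgG of either line removed. Ependymoma passed with 25 kb (3.64) and with a peak anywhere in the gene (4.03). Apart from the smaller background, the cause was not tested. Unknown read depth leaves open how many sites each list misses.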

Other observations

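The 90 tests of 18 gene families and the test of fragment sizes were chosen after the data were seen; the tests of HA fold and of Cbp against p300 were written before their results.

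For HA in both lines 4 of the 18 families passed the threshold: olfactory receptors, vomeronasal receptors, keratins and Hox genes. All had fewer genes with HA than expected from the others. Fisher's exact test takes genes as independent, but neighbouring genes can share a peak. Where members of a family lie side by side, its p-values can be too small. Of 1110 olfactory receptor genes, 0 had HA in both lines (Fisher's exact test, adjusted p = 5.51e-75), 15 had p65 in M00002, against 26.1% of other genes, 2 had H3K27ac of both antibodies and 3 p300. Vomeronasal receptors had HA at 3 of 355 (exact adjusted p = 1.33e-18), p65 at 9, H3K27ac at 3 and p300 at 9. Cytosolic keratins had 0 of 53 (exact adjusted p = 0.00365) and Hox genes 0 of 39 (exact adjusted p = 0.0293), while p65 in M00002 did not pass for either, at 10 of 53 keratins (18.9% against 24.8%, exact adjusted p = 0.765) and 4 of 39 Hox genes (exact adjusted p = 0.187). H3K27ac was low in these families as well, at 1 of 53 keratins and 0 of 39 Hox genes (both exact adjusted p = 0.00266), and p300 lay at 0 of 53 keratins (exact adjusted p = 0.0325) and 1 of 39 Hox genes (exact adjusted p = 0.503). Ribosomal protein genes carried H3K27ac of both antibodies at 36 of 97, against 19.4% of other genes (exact adjusted p = 0.000437), and HA at 13 of 97, against 14.2% (exact adjusted p = 1). Chemokine genes as a family had HA at 6 of 37 (exact adjusted p = 0.835). For olfactory receptors IgG of M00002 was low as well, at 1.44% against 5.00% (exact adjusted p = 1.01e-08).

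The HA list of M00002 is 29937 peaks long on chromosomes 1 to 19 and X and that of M00001 8504. Sharing with M00001 was 48.9% in the highest and 0.720% in the lowest class of HA fold of M00002 (ratio 67.9, 50.2 to 91.9). The ratio met what was predicted if the M00001 list holds the stronger part of the M00002 sites. In the same classes p65 of M00002 rose from 1.34% to 89.0%, so such a rise is not particular to M00001. With IgG of the same line removed, 52.3% of HA peaks of M00001 overlapped HA of M00002. The rest of the M00001 list lies outside the M00002 sites. Different fragment sizes in calling stay open: the median HA peak width of M00001 was 1.8 times that of M00002, but for HA the mark of 120 bp and the line coincide. Within M00002 the median widths were 115 bp for HA and 118 bp for p65, with the mark. In the M00002 lists without it they ran from 166 to 451 bp. IgG, without the mark in either line, had 166 bp in M00002 and 174 bp in M00001. Narrow peaks thus went with the mark, though the targets differ. The share of M00002 IgG peaks overlapped was 11.1% for HA and 9.07% for p65 of M00002, the lists with the mark, and 9.63% for ac4729, without it. For ac647 of M00002, also without it, the share was 16.4%. For the non-IgG lists of M00001, all without it, the share ran from 16.9% to 20.2%. Most lists without the mark are thus also of the other line.

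The order of Cbp and p300 depended on the peaks chosen. In the whole lists 24.2% of Cbp and 31.9% of p300 peaks overlapped HA. With −log10 q of at least 5 in both lists 53.1% of 847 and 45.1% of 1143 did. Both settings kept peaks that overlap IgG. With peaks that overlap IgG of the same line removed from all lists, the shares were 19.8% for Cbp and 28.2% for p300. With IgG of either line removed they were 14.4% and 24.3%. Among the 1000 peaks of each with the highest −log10 q and no IgG overlap, the HA share was 42.4% for p300 and 34.8% for Cbp, a difference of 7.60 percentage points (3.35 to 11.9). The interval excludes 0 and the difference stays below the bound of 10 points set beforehand, so a larger background part in the Cbp list is neither excluded nor shown.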
